A study of Rattus norvegicus with 144 samples.

How the data were processed

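Affymetrix arrays of rat liver, adrenal gland and pancreas came as 2 tables that the authors deposited, 1 with 31042 probe sets on 108 arrays (adrenal, pancreas and liver of the AMG B study) and 1 with 15866 probe sets on 36 arrays (liver of the AMG A study). Per the labels, RNA was extracted with Qiagen RNeasy midi columns and 5 ug of total RNA were labelled with biotin in a one-cycle reaction. The deposited values are in the unit score: each probe set was standardised on a linear scale to a mean near 0 and an SD near 1, and probe sets in both tables were standardised over both together. Scores ran from -9.50 to 11.9 in the larger table and from -4.51 to 10.2 in the smaller, 0 values were missing, and the highest correlation between 2 arrays was 0.769 and 0.792. Scanner software, signal summary, array scaling and dates are not given in the sources used here. The signal over background is unknown, a dim transcript weighs as much as an abundant one, and the number of arrays limits the precision.

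Probe sets were assigned to genes through the platform tables, with symbols updated by Entrez number to a RefSeq gene table of assembly GRCr8. Of the probe sets in the larger table, 20826 had 1 symbol, 436 several and 9780 none, leaving 14217 genes, 4525 of them with several probe sets. In the smaller, 12783 had 1 symbol, 312 several and 2771 none, leaving 10411 genes. A gene was represented by the probe set with the largest share of variance between tissues over the 108 arrays.

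Each group of tissue, study, dose and day (4 animals) was a term of a linear model fitted with limma 3.58.1 (lmFit, contrasts.fit, eBayes with trend) in R 4.3.3, separately for liver of each study, adrenal and pancreas, and for the tissue contrasts on day 14 of each study. The 41 contrasts were 24 of a dose against control, 6 of high against low dose, 3 of the day 14 against the day 1 effect, 4 of AMG A against AMG B effects, 2 of study controls and 2 of adrenal against pancreas effects. Tests were two-sided, with Benjamini-Hochberg adjustment within a contrast and a threshold of 0.05. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and the R package data.table (version 1.17.8) were also used. Arrays of different tables were not tested against each other. The groups, contrasts, gene lists and the rule for naming genes were chosen before the data were examined, as were the alternatives not named below as later.

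The rule named, per dose contrast, the largest rises and falls among genes with adjusted p under 0.05, every treated animal beyond every control and 1 symbol that is not a placeholder. It took up to 8 and 8 at the high dose on day 14, 4 and 4 on days 1 and 4 and 3 and 3 at the low dose. Difference contrasts gave up to 4 and 4 without the condition on overlap, each list described up to 4 members past the threshold, and Vegfa, Kdr, Flt1 and Flt4 were read everywhere. For length, not every list or gene the rule named is printed, and this choice was made after the values were seen: genes whose call ended when 1 animal was left out were dropped more often. The named genes therefore look more stable than the full set, whose counts are given with the alternatives.

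Departures from the plan followed from the unit. The model was fitted to scores rather than log2 values, no filter was applied (a percentile of scores does not tell signal strength), and the probe set with the highest mean was replaced by the choice above. A pseudocount could not be applied to scores and was not run.

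The 35 gene lists were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation, where at least 4 members were measured (28 lists in liver, 24 in adrenal, 26 in pancreas, 22 in the tissue contrasts). They covered endothelial cells, VEGF-responsive and tip-cell genes, hypoxia-inducible genes, pericytes and smooth muscle, cell cycle, extracellular matrix and fibroblasts, macrophages, lymphocytes, interferon-inducible genes, erythroid cells and blood, adipocytes, skeletal muscle, kidney, circadian clock, glucocorticoid-responsive genes, immediate early genes, ER stress, NRF2, cholesterol synthesis, fatty acid synthesis and fatty acid oxidation in every tissue, hepatocytes outside liver, and lists particular to liver, adrenal or pancreas.

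Animal numbers tie the tissues of an animal. Checked on the deviations of arrays from their group, the median correlation across genes was 0.039 between adrenal and pancreas, 0.052 between liver and adrenal and 0.029 between liver and pancreas of the same animal, against -0.011, -0.018 and -0.0068 of different animals, so the tissue contrasts were also fitted with the animal as a block. Alternatives chosen beforehand were quantile normalization, a filter on low scores (above the 40th percentile on at least 4 arrays), the mean of the probe sets, only the compared groups, each animal left out in turn, the animal as a block and the estimated correlation. Chosen after seeing the data were a log-like scale, the probe set with the highest mean, the SD of the array as a covariate and leaving out 6 pancreas arrays whose lymphocyte list mean was above 2. Simulated data had 50 genes shifted by each of 2, 4, 6 and 8 SD. The procedure recovered 22%, 98%, 100% and 100% in liver of AMG A, 16%, 88%, 98% and 98% in liver of AMG B, 18%, 92%, 98% and 98% in adrenal and 26%, 90%, 100% and 100% in pancreas. It called 8, 8, 9 and 13 unchanged genes and 0 lists, which does not test lists of correlated genes or genes whose spread differs between groups.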

Results

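Transcripts were measured on 144 arrays from 72 male Sprague Dawley rats dosed by mouth once a day with AMG A or AMG B. These compounds are known here by their code names, and the series' design text calls their pharmacology antiangiogenic. The arrays formed 36 groups of 4 animals. Liver was sampled on days 1, 4 and 14 at 0, 3 and 30 mg/kg of AMG A (36 arrays) and at 0, 3 and 60 mg/kg of AMG B (36 arrays). Adrenal gland was sampled on the same days for AMG B (36 arrays) and on day 14 for AMG A (12 arrays). Pancreas was sampled on day 14 for each compound (12 arrays each). All values are deposited scores, in which 1 unit is the standard deviation of that probe set over all arrays and 0 its mean. A difference is thus neither a fold change nor an amount of RNA. The SD of the scores on an array ran from 0.619 to 0.709 in liver of the AMG A study and from 0.793 to 0.990 in liver of the AMG B study. In adrenal it ran from 0.866 to 0.950 and from 0.822 to 1.15, and in pancreas from 1.15 to 1.64 and from 1.16 to 1.99. The number of arrays limits the precision. Values are mean ± SD of the treated animals against the controls of the same study, day and tissue (n = 4 per group), unless a difference is named. On assembly GRCr8, Cyp1a1 and Cyp1a2 lie on chromosome 8 (start 66991940 and 66971261). Tek and Slc2a1 lie on chromosome 5 (start 114722815 and 138002522), and Emcn, Fdps and Amy1 on chromosome 2 (start 228564445, 176795192 and 204071101). Vegfa lies on chromosome 9 (start 22452854) and Reg3b on chromosome 4 (start 112419776). Of 632 tests of a gene list in a dose contrast, 108 passed with a preset correlation between genes and 7 with an estimated one, so each list has both p values.

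**Figure D1:**
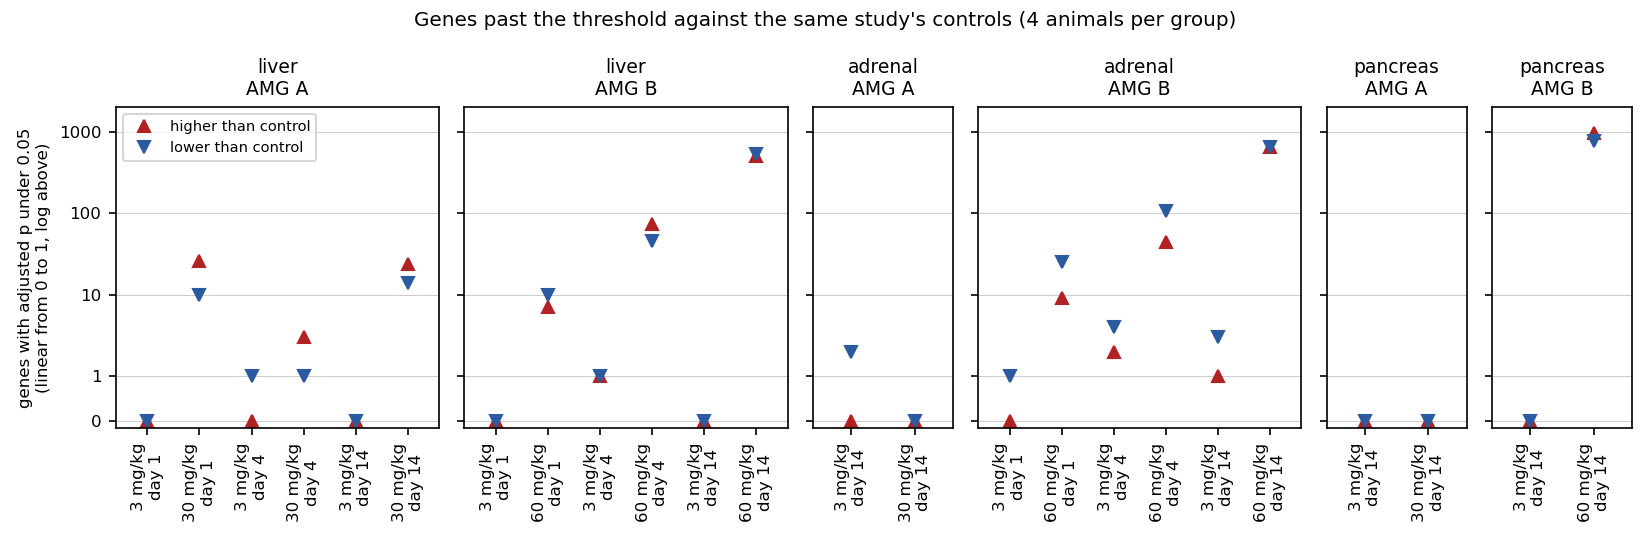
Number of genes with adjusted p under 0.05 (vertical axis, linear from 0 to 1 and logarithmic above) for each dose and day against control, by tissue and compound; upward marks are genes higher and downward marks genes lower than in the controls. At the high dose on day 14 the AMG B marks stand at 503 and 538 in liver, 642 and 653 in adrenal and 947 and 772 in pancreas.

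Which liver transcripts AMG A changed was asked first. At 30 mg/kg it raised Cyp1a2, an aryl hydrocarbon receptor target that oxidises aromatic amines, on day 1 (2.20 ± 0.12 against 0.32 ± 0.13, adjusted p = 6.9e-13). Cyp1a2 was also raised on day 4 (1.40 ± 0.14 against 0.39 ± 0.11, adjusted p = 2.9e-06) and day 14 (1.90 ± 0.29 against 0.18 ± 0.10, adjusted p = 8.0e-12). Cyp1a1, a target of the same receptor looked up after its values had been seen, did not pass on day 14 (-0.20 ± 0.043 against -0.28 ± 0.0052, adjusted p = 0.32). On day 1 Ifitm10 (0.34 ± 0.25 against -0.59 ± 0.055, adjusted p = 3.1e-06) and the circadian repressor Nr1d1 (-0.45 ± 0.28 against -1.05 ± 0.053, adjusted p = 0.0088) also rose. Ghrhr, the receptor of growth hormone-releasing hormone, fell (-0.77 ± 0.17 against 0.16 ± 0.32, adjusted p = 0.0015). On day 4 Chac1, which degrades glutathione, fell at 3 mg/kg (-0.54 ± 0.089 against -0.11 ± 0.15, adjusted p = 0.038) and at 30 mg/kg (-0.57 ± 0.033 against -0.11 ± 0.15, adjusted p = 0.0071), where Wdr59 (adjusted p = 0.036) and Frmd8 (adjusted p = 0.036) rose. On day 14 the ubiquitin ligase Siah2 (-0.0016 ± 0.21 against -0.81 ± 0.098, adjusted p = 0.0030), Mlx, a partner of carbohydrate response factors (adjusted p = 0.013), and Krt79 (adjusted p = 0.029) rose. The neuropeptide Npw fell (-0.68 ± 0.093 against 0.26 ± 0.16, adjusted p = 0.013), as did the Mediator subunit Med27 (adjusted p = 0.033) and the immediate early gene Egr2 (adjusted p = 0.0447). Of 10411 genes tested at 30 mg/kg, 36 changed on day 1 (26 up, 10 down), 4 on day 4 and 38 on day 14 (24 up, 14 down). At 3 mg/kg limma called 0 genes on day 1, 1 on day 4 and 0 on day 14, with 1061, 746 and 824 at an unadjusted p under 0.05. Against 3 mg/kg on day 14, 12 genes were higher, Cyp1a2 (1.28, adjusted p = 1.1e-08) and Siah2 (0.71, adjusted p = 0.018) among them, and Kif5a (-0.30, adjusted p = 0.040) lower. By limma the day 14 effect differed from that of day 1 in 0 genes, with 489 at an unadjusted p under 0.05 (1 without animal 3009 or 3034). Of 21 drug-metabolising enzymes 1 rose, and adjusted over the list alone 2 (adjusted p = 0.28, adjusted p = 0.52 with an estimated correlation). At 30 mg/kg the count was 9 without animal 3003, 10 without 3025, 14 without 3004, 15 without 3001, 21 without 3028, 22 without 3027 and 75 without 3002 on day 1. It was 1 without animal 3008, 2 without 3005, 3032 or 3030 and 9 without 3007 on day 4, and 7 without animal 3010, 11 without 3036, 13 without 3011, 14 without 3034 and 118 without 3035 on day 14. The 3 mg/kg count was 1 without animal 3001, 2 without 3015, 15 without 3002 and 26 without 3013 on day 1. It was 0 without animal 3008, 3019, 3020 or 3017, 2 without 3006 and 3 without 3007 on day 4, and 1 without animal 3010 and 3 without 3023 on day 14. For 30 against 3 mg/kg it was 1 without animal 3022, 3036 or 3034, 3 without 3021, 5 without 3024, 20 without 3023 and 35 without 3033. The calls of Chac1 at 30 mg/kg on day 4 (without 3008), Wdr59, Frmd8, Med27 and Kif5a (6 of 8 omissions), Chac1 at 3 mg/kg on day 4, Krt79 and Egr2 (5 of 8 omissions), Mlx (without 3010, 3011 and 3036), Npw (without 3010 and 3034) and Siah2 at 30 against 3 mg/kg on day 14 (4 of 8 omissions) ended with 1 animal left out, at adjusted p from 0.0508 to 0.31. Another probe set of Kif5a differed in the opposite direction, and the sign turned (0.14 with the probe set of the highest mean).

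In liver of the AMG B study, 60 mg/kg raised both aryl hydrocarbon receptor targets on day 1, Cyp1a1 (2.43 ± 0.98 against -0.31 ± 0.0027, adjusted p = 4.7e-07) and Cyp1a2 (1.41 ± 0.064 against 0.49 ± 0.13, adjusted p = 0.00015). Ifitm10 rose with them (1.92 ± 0.38 against -0.16 ± 0.071, adjusted p = 1.2e-07). The scavenger receptors of sinusoidal endothelium, Stab2 (-0.26 ± 0.30 against 2.19 ± 0.85, adjusted p = 0.034) and Lyve1 (0.29 ± 0.37 against 2.31 ± 0.46, adjusted p = 0.013), fell on day 1, as did Fam167b (adjusted p = 0.0010). On day 4, of 36 cell cycle genes 10 rose, and adjusted over the list alone 18 (adjusted p = 1.2e-16, adjusted p = 0.038 with an estimated correlation). Among them were Cdkn3 (2.91 ± 0.71 against -0.35 ± 0.38, adjusted p = 2.0e-06), the mitotic kinase Cdk1 (1.57 ± 0.44 against -0.38 ± 0.40, adjusted p = 0.0012) and Kif20a (adjusted p = 7.3e-05). Of 20 cholesterol synthesis genes 4 rose, and adjusted over the list alone 11 (adjusted p = 4.8e-14, adjusted p = 0.038 with an estimated correlation), such as Dhcr7 (adjusted p = 0.0061) and Msmo1 (adjusted p = 0.010). Of 10 erythroid genes 2 fell, and adjusted over the list alone 5 (adjusted p = 2.1e-05, adjusted p = 0.027 with an estimated correlation). Alas2, the first enzyme of haem synthesis in red cells (-1.10 ± 0.14 against 1.36 ± 1.01, adjusted p = 0.0011), and the globin Hbb (-1.48 ± 0.12 against 0.37 ± 0.43, adjusted p = 2.0e-06) were lower. Endothelial genes were lower as a list, while of 25 members 0 passed, and adjusted over the list alone 5 fell (adjusted p = 9.1e-06, adjusted p = 0.032 with an estimated correlation). Of 17 interferon-inducible genes 3 rose, and adjusted over the list alone 7 (adjusted p = 5.5e-08, adjusted p = 0.096 with an estimated correlation), with the proteasome subunit Psmb9 higher (adjusted p = 0.0015). Mrc1, the mannose receptor of macrophages (-0.19 ± 0.30 against 1.36 ± 0.37, adjusted p = 0.00079), and the matrix protein Sparc (-1.15 ± 0.047 against -0.78 ± 0.088, adjusted p = 0.0011) fell. Of 14217 genes 17 changed on day 1 (7 up, 10 down) and 120 on day 4 (74 up, 46 down). At 3 mg/kg on day 4 Mtmr7 rose (3.64 ± 0.28 against 1.16 ± 0.18, adjusted p = 3.3e-05) and the globin Hba-a3 fell (-0.55 ± 0.34 against 0.89 ± 0.83, adjusted p = 0.043). On days 1 and 14 limma called 0 genes at 3 mg/kg, with 653 and 957 at an unadjusted p under 0.05. At 60 mg/kg the count was 9 without animal 12 and 11 without 4 on day 1 and 50 without animal 23, 61 without 14, 64 without 21 and 71 without 16 on day 4. The 3 mg/kg count was 1 without animal 15, 19 or 20 and 5 without 13 on day 4 and 2 without animal 30 and 6 without 32 on day 14. The calls of Stab2 (7 of 8 omissions), Lyve1 (without 4, 11 and 12), Msmo1 (without 23) and Hba-a3 (5 of 8 omissions) ended with 1 animal left out, at adjusted p from 0.0525 to 0.24.

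**Figure D2:**
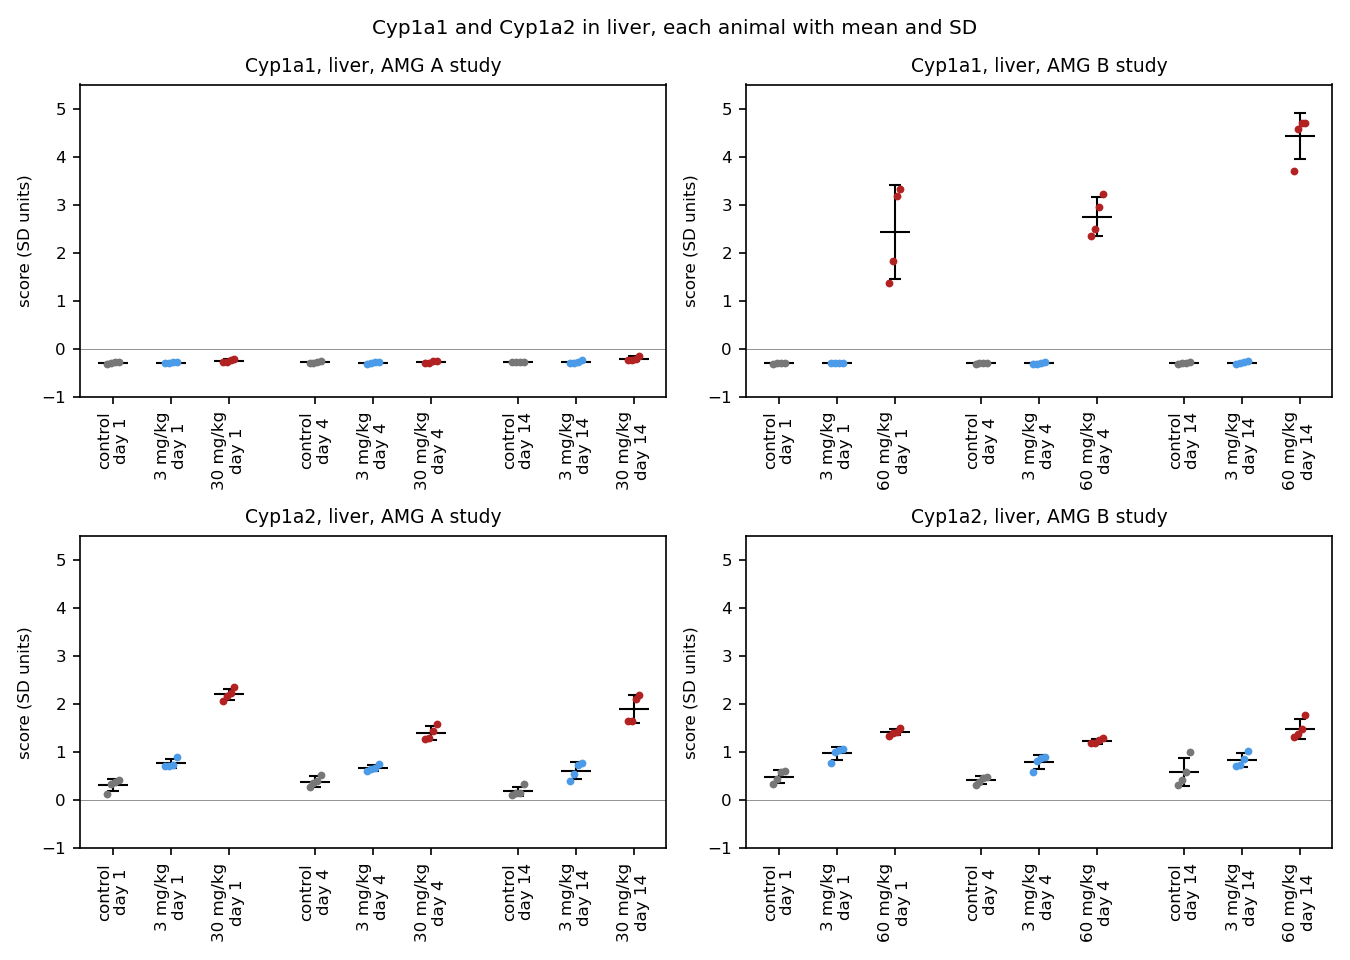
Scores (SD units, vertical axis) of Cyp1a1 and Cyp1a2 in liver by dose and day in the AMG A and AMG B studies; points are animals, bars mean and SD of 4. Cyp1a1 stood at 4.42 ± 0.48 against -0.30 ± 0.018 at 60 mg/kg of AMG B on day 14 and at -0.20 ± 0.043 against -0.28 ± 0.0052 at 30 mg/kg of AMG A.

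By day 14 the liver response to AMG B at 60 mg/kg covered 1041 genes (503 up, 538 down). Of all 14217 genes, treated and control animals did not overlap in 1551 (10.91%), where chance gives 2.86%. Among xenobiotic enzymes Cyp1a1 (4.42 ± 0.48 against -0.30 ± 0.018, adjusted p = 1.3e-12), the glutathione transferase Gsta3 (3.87 ± 2.03 against 0.66 ± 0.33, adjusted p = 0.0010) and Cyp3a9 (adjusted p = 0.0038) rose. Of 21 drug-metabolising enzymes 5 rose and 2 fell, and adjusted over the list alone 6 rose and 2 fell (adjusted p = 0.0034, adjusted p = 0.13 with an estimated correlation). The quinone reductase Nqo1 rose (3.77 ± 0.96 against 1.04 ± 0.17, adjusted p = 0.00022), and of 12 NRF2 genes 2 rose, and adjusted over the list alone 3 (adjusted p = 0.025, adjusted p = 0.13 with an estimated correlation). Of 19 acute phase genes 3 rose, and adjusted over the list alone 12 (adjusted p = 1.7e-09, adjusted p = 0.13 with an estimated correlation). They included the interleukin 1 receptor antagonist Il1rn (3.43 ± 0.85 against 0.36 ± 0.43, adjusted p = 2.5e-06) and the lipopolysaccharide-binding Lbp (3.47 ± 1.17 against 1.27 ± 0.097, adjusted p = 0.00050). Acmsd of the kynurenine pathway (4.62 ± 1.31 against 0.50 ± 0.50, adjusted p = 2.9e-05), the citrate transporter Slc13a5 (4.01 ± 2.41 against 0.10 ± 0.45, adjusted p = 0.00053) and Ly75 (adjusted p = 1.6e-05) also rose. Of 16 macrophage markers 11 fell, and adjusted over the list alone 1 rose and 13 fell (adjusted p = 1.7e-09, adjusted p = 0.13 with an estimated correlation). That list mean was 0.80 in animal 35, near the control mean of 0.97, against -0.47 to -0.18 in the other 3. Mrc1 (-0.21 ± 0.39 against 1.52 ± 0.47, adjusted p = 4.3e-05) and the complement chain C1qa (-0.36 ± 0.80 against 1.35 ± 0.57, adjusted p = 0.0055) fell, beside the cytokine Il1b (-0.84 ± 0.35 against 1.85 ± 0.32, adjusted p = 0.00036). Of 19 fatty acid oxidation genes 5 fell, and adjusted over the list alone 7 (adjusted p = 4.7e-05, adjusted p = 0.23 with an estimated correlation), such as Angptl4 (-1.24 ± 1.06 against 0.93 ± 0.81, adjusted p = 0.0085). That list mean was -0.49 in animal 35 and 0.13 to 0.79 in the other 3, around the control mean of 0.63. Of 14 fatty acid synthesis genes 3 fell, and adjusted over the list alone 4 (adjusted p = 0.076, adjusted p = 0.40 with an estimated correlation). These were the desaturases Fads1 (adjusted p = 0.0026) and Fads2 (-0.92 ± 0.18 against 0.46 ± 0.50, adjusted p = 0.0033) and the elongase Elovl5 (adjusted p = 0.0020). Other falls were Alas2 (-0.96 ± 0.12 against 1.49 ± 0.39, adjusted p = 0.00032), Hbb (adjusted p = 1.5e-06) and Ric3 (adjusted p = 0.0015). The count was 664 without animal 26 and 679 without 25, and 54 with only the compared groups fitted. The call of NRF2 oxidative stress response (without 34) ended with 1 animal left out, at adjusted p = 0.13.

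Lists of vessel and matrix genes were lower in the same livers. Of 25 endothelial genes 7 fell, and adjusted over the list alone 1 rose and 9 fell (adjusted p = 0.0017, adjusted p = 0.13 with an estimated correlation). The angiopoietin receptor Tek (-1.46 ± 0.30 against -0.43 ± 0.55, adjusted p = 0.023) and the sphingosine phosphate receptor S1pr1 (-0.10 ± 0.67 against 0.97 ± 0.51, adjusted p = 0.021) fell. Of 19 VEGF-responsive genes 3 fell, and adjusted over the list alone 1 rose and 6 fell (adjusted p = 0.013, adjusted p = 0.13 with an estimated correlation), with Igfbp3 lower (-0.22 ± 0.45 against 1.14 ± 0.22, adjusted p = 0.0038). Of 18 matrix genes 6 fell, and adjusted over the list alone 1 rose and 6 fell (adjusted p = 0.0021, adjusted p = 0.23 with an estimated correlation). Col3a1 (-0.67 ± 0.14 against 0.053 ± 0.10, adjusted p = 0.0021) and Sparc (-1.14 ± 0.091 against -0.70 ± 0.049, adjusted p = 2.6e-05) fell. Of 10 stellate cell genes 1 rose and 2 fell, and adjusted over the list alone 1 rose and 3 fell (adjusted p = 0.54, adjusted p = 0.68 with an estimated correlation). The rise was Rgs5 (1.31 ± 0.65 against 0.023 ± 0.36, adjusted p = 0.0049), and Lrat, which esterifies retinol, fell (-0.64 ± 0.027 against -0.41 ± 0.046, adjusted p = 0.0011). Of 13 growth hormone and male-pattern genes 2 fell, and adjusted over the list alone 2 (adjusted p = 0.00075, adjusted p = 0.23 with an estimated correlation). The falls were Igfals (0.32 ± 0.34 against 1.61 ± 0.33, adjusted p = 0.00088) and Igf1 (1.00 ± 0.074 against 1.40 ± 0.11, adjusted p = 0.0063), both driven by growth hormone. Of 25 hypoxia-inducible genes 3 rose and 1 fell, and adjusted over the list alone 5 rose and 2 fell (adjusted p = 0.25, adjusted p = 0.40 with an estimated correlation), with Egln3 higher (adjusted p = 0.0023). Against 3 mg/kg 747 genes changed (421 up, 326 down). Cyp1a1 (4.71, adjusted p = 1.3e-12), Acmsd (4.24, adjusted p = 6.5e-05) and Slc13a5 (3.40, adjusted p = 0.0033) were higher and Ric3 (-2.56, adjusted p = 0.0015) lower. The day 14 effect differed from that of day 1 in 42 genes (24 up, 18 down). It was higher for Il1rn (3.15, adjusted p = 0.0031), Ly75 (3.12, adjusted p = 0.0042) and Cyp1a1 (1.99, adjusted p = 0.022). Against 3 mg/kg the count was 360 without animal 30 and 447 without 29, and 6 with only the compared groups fitted. For day 14 minus day 1 it was 12 without animal 28, 18 without 26, 21 without 3, 22 without 10, 25 without 11, 71 without 33 and 98 without 36. The calls of Tek (5 of 8 omissions), S1pr1 (without 27, 28 and 35) and growth-hormone and male-pattern liver genes (without 35) ended with 1 animal left out, at adjusted p from 0.0519 to 0.59.

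Adrenal glands of the AMG A study, sampled to set beside those of AMG B, differed from their controls in few genes. At 3 mg/kg Sgf29, a reader of histone marks, fell (-1.25 ± 0.28 against -0.37 ± 0.28, adjusted p = 0.0461). The vitamin D receptor Vdr, named after its values were seen, was the other of 2 genes called (-1.67, adjusted p = 0.046). At 30 mg/kg limma called 0 of 14217 genes, with 847 at an unadjusted p under 0.05. For 30 against 3 mg/kg it also called 0, with 819 at an unadjusted p under 0.05. Cholesterol synthesis was higher as a list at 30 mg/kg, while of 20 genes 0 passed, also adjusted over the list alone (adjusted p = 7.0e-08, adjusted p = 0.34 with an estimated correlation). Immediate early genes were lower, and of 14 members 0 passed, and adjusted over the list alone 1 fell (adjusted p = 5.6e-05, adjusted p = 0.26 with an estimated correlation). Fat cell markers were higher, and of 10 members 0 passed, also adjusted over the list alone (adjusted p = 0.0017, adjusted p = 0.46 with an estimated correlation). Steroid synthesis was higher at 3 mg/kg, where of 16 genes 0 passed, also adjusted over the list alone (adjusted p = 9.1e-05, adjusted p = 0.36 with an estimated correlation). At 3 mg/kg the count was 0 without animal 3022, 3021, 3012, 3024 or 3009 and 4 without 3023. At 30 mg/kg it was 3 without animal 3033, and for 30 against 3 mg/kg 1 without animal 3036 or 3034 and 2 without 3033. The calls of Sgf29 (6 of 8 omissions), steroid synthesis (without 3009) and adipocytes (without 3035) ended with 1 animal left out, at adjusted p from 0.095 to 0.32.

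In adrenal glands, of 25 endothelial genes 2 fell, and adjusted over the list alone 7 (adjusted p = 5.8e-06, adjusted p = 0.15 with an estimated correlation) at 60 mg/kg of AMG B on day 1. Tek (0.13 ± 0.17 against 2.22 ± 0.37, adjusted p = 1.1e-06), the sialomucin Emcn (0.56 ± 0.093 against 1.91 ± 0.29, adjusted p = 0.00047) and Dysf, which reseals membranes (adjusted p = 0.0059), fell. The complement chains C1qb (-1.06 ± 0.061 against -0.31 ± 0.38, adjusted p = 0.0085) and C1qc (-1.43 ± 0.070 against -0.58 ± 0.45, adjusted p = 0.0053), made by macrophages, fell as well. Of 16 macrophage markers 3 fell, and adjusted over the list alone 7 (adjusted p = 3.0e-09, adjusted p = 0.11 with an estimated correlation). On day 4, of 25 endothelial genes 8 fell, and adjusted over the list alone 15 (adjusted p = 1.3e-17, adjusted p = 0.0044 with an estimated correlation), a fall under either correlation. Tie1 (-0.70 ± 0.66 against 1.95 ± 0.55, adjusted p = 0.0011), Emcn (0.089 ± 0.070 against 2.05 ± 0.38, adjusted p = 3.4e-07) and Tek (-0.27 ± 0.14 against 1.39 ± 0.64, adjusted p = 6.5e-05) were among them. The VEGF receptor Flt1 (-0.35 ± 0.25 against 0.79 ± 0.20, adjusted p = 0.022), the VEGF co-receptor Nrp1 (-0.66 ± 0.18 against 2.09 ± 0.94, adjusted p = 0.0038) and the pericyte marker Rgs5 (adjusted p = 0.0024) fell too. Pnmt, which makes adrenaline, rose (2.50 ± 1.22 against 0.34 ± 0.12, adjusted p = 0.010). Of 17 medulla genes 1 rose, and adjusted over the list alone 1 (adjusted p = 0.00059, adjusted p = 0.23 with an estimated correlation). Of 20 cholesterol synthesis genes 3 rose, and adjusted over the list alone 12 (adjusted p = 3.6e-13, adjusted p = 0.22 with an estimated correlation), Tm7sf2 among them (adjusted p = 0.0098). At 60 mg/kg 34 genes changed on day 1 (9 up, 25 down) and 150 on day 4 (44 up, 106 down). At 3 mg/kg Car8 fell on day 1 (-0.98 ± 0.042 against -0.72 ± 0.067, adjusted p = 0.0036), the single gene called. On day 4, 6 genes changed, with Marf1 up (adjusted p = 0.0016) and Fam167b down (-0.59 ± 0.17 against 0.87 ± 0.084, adjusted p = 0.00040). On day 14, 4 changed, with Tbl1x up (adjusted p = 0.0012) and Fam167b (0.39 ± 0.34 against 1.51 ± 0.44, adjusted p = 0.020) and Creg2 (adjusted p = 0.030) down. Scgb3a1, named after its values were seen, was the other (-1.03, adjusted p = 0.020). The 60 mg/kg count was 22 without animal 3 on day 1. It was 79 without animal 16, 81 without 13 and 230 without 15 on day 4, and 266 on a log-like scale and 15 with only the compared groups fitted. The 3 mg/kg count was 0 without animal 3 and 2 without 8, 2 or 4 on day 1. It was 2 without animal 17 or 13, 10 without 14 and 18 without 18 on day 4, and 2 without animal 27 or 32, 7 without 25 or 30 and 11 without 31 on day 14. The calls of C1qb (without 4), C1qc and Car8 (without 3), Flt1 (without 13, 22 and 24), Pnmt and adrenal medulla (without 22), Tm7sf2 (without 21 and 23), Fam167b at 3 mg/kg on day 14 (without 25, 27 and 32) and Creg2 (6 of 8 omissions) ended with 1 animal left out, at adjusted p from 0.0521 to 0.25. Another probe set of Tbl1x differed in the opposite direction, and the sign turned (-0.057 with the mean of the probe sets).

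**Figure D3:**
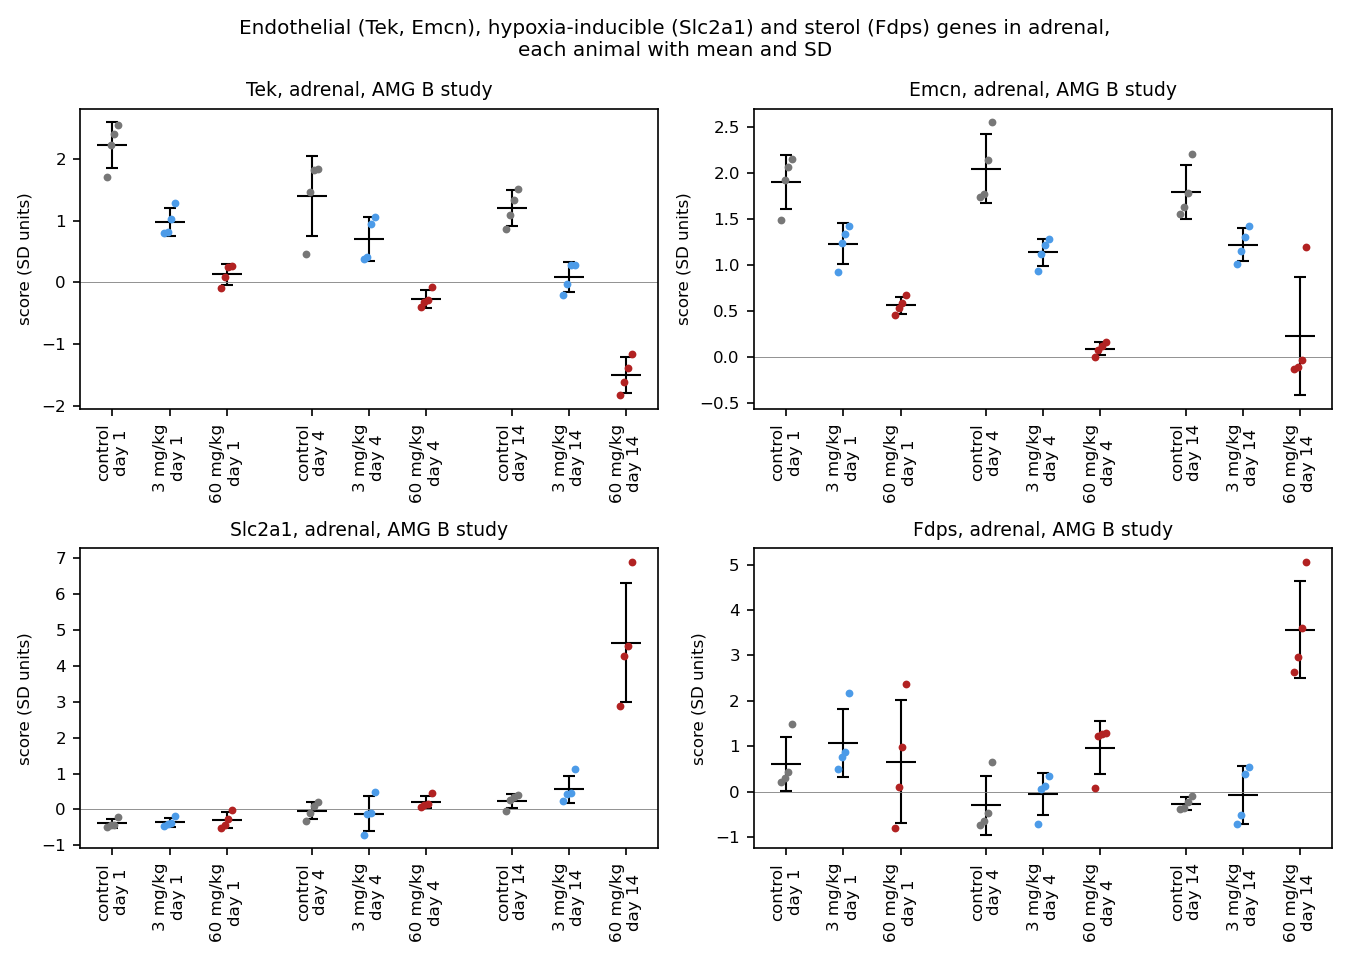
Scores (SD units, vertical axis) of the endothelial genes Tek and Emcn, the glucose transporter Slc2a1 and the sterol enzyme Fdps in adrenal by AMG B dose and day; points are animals, bars mean and SD of 4. Tek at 60 mg/kg stood at 0.13 ± 0.17 against 2.22 ± 0.37 on day 1 and -1.50 ± 0.29 against 1.20 ± 0.28 on day 14.

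On day 14 at 60 mg/kg of AMG B, 1295 adrenal genes changed (642 up, 653 down). Of all 14217 genes, treated and control animals did not overlap in 1757 (12.36%), where chance gives 2.86%. Of 25 hypoxia-inducible genes 16 rose, and adjusted over the list alone 20 (adjusted p = 7.2e-22, adjusted p = 0.00055 with an estimated correlation). These included the glucose transporter Slc2a1 (4.64 ± 1.67 against 0.24 ± 0.20, adjusted p = 1.7e-10), the hexokinase Hk2 (3.79 ± 2.55 against 0.28 ± 0.79, adjusted p = 0.00012) and the mitophagy receptor Bnip3 (adjusted p = 1.1e-05). Of 20 cholesterol synthesis genes 17 rose, and adjusted over the list alone 18 (adjusted p = 1.0e-25, adjusted p = 0.032 with an estimated correlation). Fdps (3.57 ± 1.07 against -0.27 ± 0.14, adjusted p = 2.4e-06), Lss (3.69 ± 1.40 against 0.24 ± 0.27, adjusted p = 1.0e-05) and Sqle (adjusted p = 2.0e-05) were among them. The haem oxygenase Hmox1 (4.44 ± 3.70 against -0.19 ± 0.19, adjusted p = 5.6e-05) and the lipid carrier Fabp6 (4.56 ± 1.85 against -0.17 ± 0.12, adjusted p = 1.0e-06) were among the largest rises. So was Fabp5 (adjusted p = 4.6e-11). Of 25 endothelial genes 6 fell, and adjusted over the list alone 8 (adjusted p = 5.2e-06, adjusted p = 0.12 with an estimated correlation). Animal 35 went against this, with a list mean of 1.06 above the control mean of 0.71 and -0.44 to -0.21 in the other 3. Tek (-1.50 ± 0.29 against 1.20 ± 0.28, adjusted p = 3.3e-10), Tie1 (-1.11 ± 0.86 against 1.64 ± 0.64, adjusted p = 0.00010) and Emcn (0.23 ± 0.65 against 1.80 ± 0.29, adjusted p = 4.0e-06) fell. Esm1, a gene of endothelial tip cells, rose (3.98 ± 3.75 against 0.62 ± 0.35, adjusted p = 0.0039). Of 16 macrophage markers 6 fell, and adjusted over the list alone 10 (adjusted p = 5.9e-07, adjusted p = 0.12 with an estimated correlation), such as C1qc (-1.24 ± 0.31 against -0.26 ± 0.23, adjusted p = 4.1e-05). Here too animal 35 (0.085) lay above the control mean of -0.21, and the other 3 from -1.03 to -0.84. Of 36 cell cycle genes 11 rose, and adjusted over the list alone 18 rose and 1 fell (adjusted p = 2.1e-09, adjusted p = 0.12 with an estimated correlation), and without animal 35, 5 rose. Of 21 ER stress genes 7 rose, and adjusted over the list alone 9 (adjusted p = 1.4e-05, adjusted p = 0.061 with an estimated correlation), with Pdia6 higher (adjusted p = 0.0034). Animal 35 had a matrix list mean of 4.10, against -0.35 to -0.23 in the other 3. That list was higher with animal 35, where of 18 genes 0 passed, also adjusted over the list alone (adjusted p = 0.00070, adjusted p = 0.57 with an estimated correlation), and lower without it (adjusted p = 0.034). The clock gene Bhlhe40 (adjusted p = 3.4e-05) and the metallothionein Mt1 (adjusted p = 0.0061) rose. The amino acid enzyme Ivd (-1.12 ± 0.39 against 1.48 ± 0.30, adjusted p = 4.2e-05), the oxidation enzyme Ech1 (adjusted p = 0.0086), Rgs5 (adjusted p = 0.00095) and Fam167b (adjusted p = 4.6e-11) fell. Against 3 mg/kg 1006 genes changed (518 up, 488 down), with Hmox1 (4.74, adjusted p = 5.5e-05) and Slc2a1 (4.08, adjusted p = 1.5e-09) higher. There, of 25 hypoxia-inducible genes 19 were higher, and adjusted over the list alone 20 (adjusted p = 4.3e-27, adjusted p = 8.9e-05 with an estimated correlation). Likewise, of 20 cholesterol synthesis genes 17 were higher, and adjusted over the list alone 18 (adjusted p = 1.6e-26, adjusted p = 0.030 with an estimated correlation). The day 14 effect differed from that of day 1 in 303 genes (170 up, 133 down), Slc2a1 among the higher (4.31, adjusted p = 4.2e-06). In that contrast, of 25 hypoxia-inducible genes 13 were higher, and adjusted over the list alone 16 (adjusted p = 3.3e-17, adjusted p = 0.0030 with an estimated correlation). Counts with only the compared groups fitted were 158 against control and 4 against 3 mg/kg, and 603 after quantile normalization against 3 mg/kg. For day 14 minus day 1 the count was 185 without animal 11, 190 without 12, 194 without 25, 196 without 4 and 457 without 34.

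Pancreas was sampled on day 14 alone, and AMG B at 60 mg/kg lowered the digestive enzyme genes of its acinar cells. Of 27 acinar genes 23 fell, and adjusted over the list alone 24 (adjusted p = 9.3e-27, adjusted p = 0.24 with an estimated correlation). The amylases Amy1 (-0.38 ± 0.38 against 1.19 ± 0.093, adjusted p = 0.00031) and Amy2a3 (1.53 ± 0.082 against 2.72 ± 0.27, adjusted p = 0.00044) and the chymotrypsinogen Ctrb1 (adjusted p = 0.00025) fell. Of 14 injury and regeneration genes 5 rose and 1 fell, and adjusted over the list alone 6 rose and 1 fell (adjusted p = 0.0026, adjusted p = 0.33 with an estimated correlation). The secreted lectins Reg3b (5.34 ± 0.15 against 1.05 ± 0.79, adjusted p = 4.1e-06) and Reg3a (4.96 ± 0.18 against 1.45 ± 0.93, adjusted p = 3.1e-05) rose, while the trefoil factor Tff2 fell (adjusted p = 0.0037). Of 21 ER stress genes 7 rose and 2 fell, and adjusted over the list alone 9 rose and 2 fell (adjusted p = 0.0086, adjusted p = 0.54 with an estimated correlation). The stress factor Ddit3 (3.94 ± 2.92 against -0.38 ± 0.15, adjusted p = 0.0030) and the pseudokinase Trib3 (adjusted p = 0.012) rose. Of 36 cell cycle genes 9 rose, and adjusted over the list alone 16 (adjusted p = 2.9e-05, adjusted p = 0.49 with an estimated correlation), among them Mki67 (3.89 ± 2.43 against 0.10 ± 0.21, adjusted p = 0.0080) and Cenpf (adjusted p = 0.0014). The insulin genes Ins2 (1.69 ± 0.089 against 2.52 ± 0.17, adjusted p = 0.013) and Ins1 (adjusted p = 0.027) fell, and of 20 islet genes 3 fell, and adjusted over the list alone 3 (adjusted p = 0.33, adjusted p = 0.92 with an estimated correlation). Muc1 fell (1.11 ± 0.31 against 2.70 ± 0.18, adjusted p = 0.00023) among duct genes. Of 9 members 1 rose and 1 fell, and adjusted over the list alone 2 rose and 1 fell (adjusted p = 0.24, adjusted p = 0.85 with an estimated correlation). Vegfa rose (-0.098 ± 0.29 against -1.15 ± 0.11, adjusted p = 0.00029) and its receptor Kdr fell (-0.50 ± 0.14 against 0.23 ± 0.11, adjusted p = 0.0092). Of 25 endothelial genes 5 fell, and adjusted over the list alone 6 (adjusted p = 0.077, adjusted p = 0.66 with an estimated correlation), Tek among the lower (-1.22 ± 0.40 against 0.40 ± 0.69, adjusted p = 0.0071). Contractile Acta2 rose (1.24 ± 1.68 against -1.04 ± 0.40, adjusted p = 0.017), and of 12 pericyte genes 3 rose, and adjusted over the list alone 3 (adjusted p = 0.064, adjusted p = 0.59 with an estimated correlation). Of 17 interferon-inducible genes 3 rose, and adjusted over the list alone 3 (adjusted p = 0.0086, adjusted p = 0.54 with an estimated correlation), Cxcl10 among them (adjusted p = 0.036). Per1 rose (-0.53 ± 0.26 against -1.90 ± 0.16, adjusted p = 0.0017). Other large rises were N4bp2l1 (3.83 ± 1.90 against -0.99 ± 0.29, adjusted p = 0.00050) and Gabrg1 (adjusted p = 0.0036). Large falls were Nell1 (-4.23 ± 2.19 against 0.87 ± 0.78, adjusted p = 0.0017), the neurotensin receptor Ntsr1 (adjusted p = 7.6e-05) and the incretin Gip (adjusted p = 0.00055). In all 1719 of 14217 genes changed (947 up, 772 down), and 2705 (19.03%) had no overlap, where chance gives 2.86%. Single arrays were high in markers of other cells, for which no cause was tested. At 60 mg/kg the lymphocyte list mean was 4.12 in animal 33 and the skeletal muscle mean 3.14 in animal 36, and control animal 28 had an adipocyte mean of 2.13. Of 13 lymphocyte genes 0 passed, also adjusted over the list alone (adjusted p = 0.65, adjusted p = 0.98 with an estimated correlation). The count was 1001 without animal 26 and 1105 without 33, and 857 with only the compared groups fitted. The calls of ER stress and amino acid response (without 36), Ins1 (4 of 8 omissions), Acta2 (without 26 and 33), interferon-inducible genes (without 33) and Cxcl10 (6 of 8 omissions) ended with 1 animal left out, at adjusted p from 0.0539 to 0.12.

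**Figure D4:**
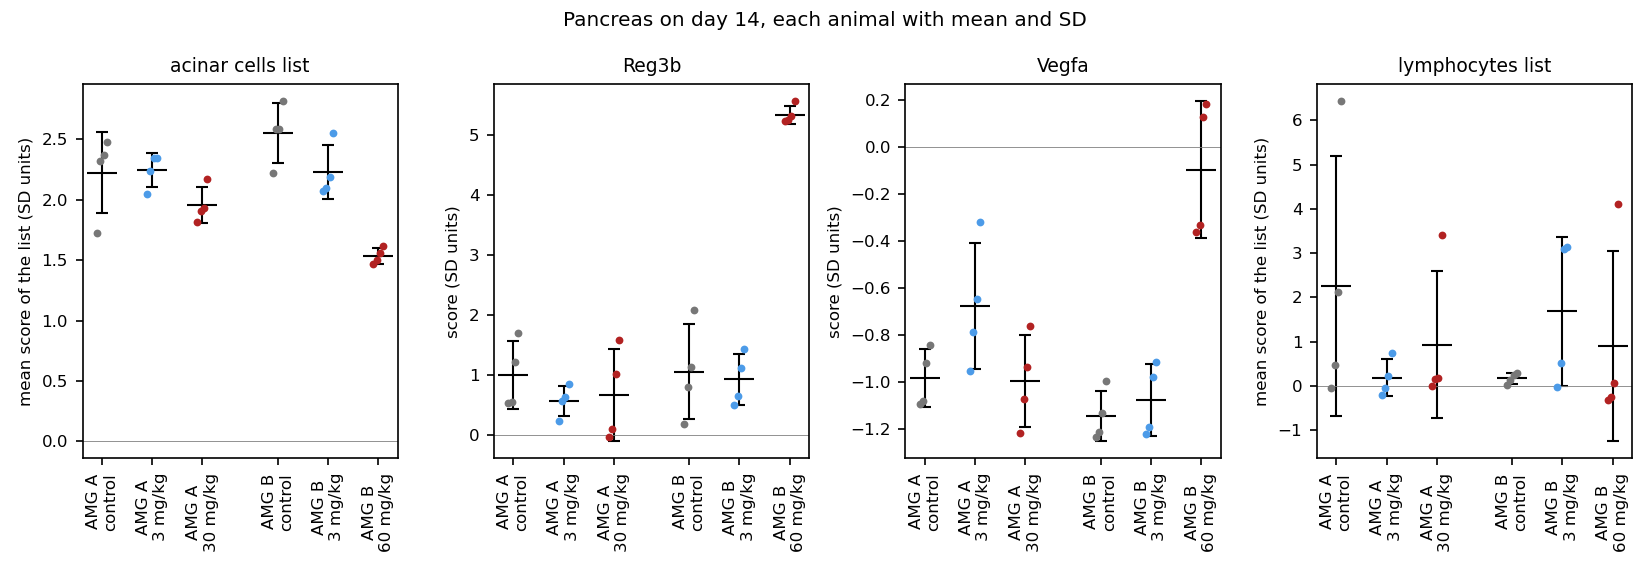
Scores (SD units, vertical axes) in pancreas on day 14 by compound and dose: mean of the acinar list, Reg3b, Vegfa and mean of the lymphocyte list; points are animals, bars mean and SD of 4. The acinar mean lay from 1.47 to 1.62 at 60 mg/kg of AMG B and from 2.22 to 2.81 in its controls.

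The lower dose of AMG B and both doses of AMG A left the pancreas with 0 genes called by limma. At an unadjusted p under 0.05 there were 556 genes at 3 mg/kg and 1052 at 30 mg/kg of AMG A, 832 for 30 against 3 mg/kg and 1263 at 3 mg/kg of AMG B. Acinar genes were lower as a list at 30 mg/kg of AMG A, where of 27 members 0 passed, also adjusted over the list alone (adjusted p = 1.9e-08, adjusted p = 0.83 with an estimated correlation). They were lower at 3 mg/kg of AMG B, where of 27 members 0 passed, also adjusted over the list alone (adjusted p = 2.9e-08, adjusted p = 0.93 with an estimated correlation). Lymphocyte genes were lower at 3 mg/kg of AMG A, where of 13 members 0 passed, also adjusted over the list alone (adjusted p = 1.5e-06, adjusted p = 0.50 with an estimated correlation) and control animal 3009 had a list mean of 6.42. They were higher at 3 mg/kg of AMG B, where of 13 members 0 passed, also adjusted over the list alone (adjusted p = 0.014, adjusted p = 0.93 with an estimated correlation) and animals 29 and 31 had means of 3.15 and 3.09. The skeletal muscle mean was 6.84 in animal 3036 at 30 mg/kg of AMG A. At 60 against 3 mg/kg of AMG B 713 genes changed (493 up, 220 down). Reg3b (4.42, adjusted p = 2.2e-06) and Atf3 (4.27, adjusted p = 0.0090) were higher, and Amy1 (-1.43, adjusted p = 0.0013) and Prrt3 (-4.03, adjusted p = 2.2e-06) lower. Of 27 acinar genes 21 were lower, and adjusted over the list alone 23 (adjusted p = 4.7e-21, adjusted p = 0.25 with an estimated correlation). The count was 1 without animal 3009 and 31 without 3034 at 30 mg/kg of AMG A and 1 without animal 25 or 27, 2 without 26 and 4 without 30 at 3 mg/kg of AMG B. At 60 against 3 mg/kg it was 302 without animal 30, 426 without 35 and 441 without 32, and 454 with the filter on low scores, 392 on a log-like scale and 5 with only the compared groups fitted. The calls of lymphocytes at 3 mg/kg of AMG B (without 29 and 31) and lymphocytes at 3 mg/kg of AMG A (without 3009) ended with 1 animal left out, at adjusted p from 0.0542 to 0.22.

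Whether the compounds differed could be asked at a matched dose of 3 mg/kg on day 14, each effect taken against its own controls. In adrenal the effect of AMG A lay below that of AMG B for Sgf29 (-1.41, adjusted p = 0.0087), Tbl1x (-1.34, adjusted p = 0.036) and Msl1 (-1.32, adjusted p = 0.037), the 3 genes called. In pancreas limma called 0, with 1488 at an unadjusted p under 0.05. The high doses differ, 30 mg/kg of AMG A and 60 mg/kg of AMG B. There 309 adrenal genes differed (147 up, 162 down in AMG A relative to AMG B). Slc2a1 (-4.50, adjusted p = 3.0e-06) and Hmox1 (-4.63, adjusted p = 0.014) were lower and Tek (1.92, adjusted p = 0.0021) and Ivd (2.74, adjusted p = 0.0079) higher. Of 25 hypoxia-inducible genes 11 were lower, and adjusted over the list alone 16 (adjusted p = 2.2e-17, adjusted p = 0.0025 with an estimated correlation). In pancreas 733 genes differed (363 up, 370 down). Reg3b (-4.62, adjusted p = 0.00054), Reg3a (-3.98, adjusted p = 0.0012) and Vegfa (-1.06, 95% interval -1.50 to -0.62, adjusted p = 0.0085) were lower, and Ndufc1 (5.16, adjusted p = 0.0019) higher. Of 27 acinar genes 3 were higher, and adjusted over the list alone 24 (adjusted p = 1.0e-11, adjusted p = 0.45 with an estimated correlation). Study controls differed in 242 adrenal genes (99 up, 143 down in the AMG A study). The vitamin D receptor Vdr (2.86 ± 0.96 against 0.12 ± 0.37, adjusted p = 1.6e-06) was higher and Loxl3 lower (adjusted p = 0.00045). In pancreas 11 differed (2 up, 9 down), with Ntsr1 lower (-0.37 ± 0.26 against 3.51 ± 0.43, adjusted p = 0.0065). Across genes, which are not independent replicates, the high-dose day 14 effects of the compounds correlated with Pearson's r of 0.078 in liver (Spearman's rho 0.071). The values were 0.0995 in adrenal (0.073) and -0.24 in pancreas (-0.25). Pearson's r was 0.044 without animal 3009 and 0.048 without 3035 in liver, and 0.031 without 3034 and 0.053 without 3009 in adrenal. In pancreas it was -0.048 without 3009, -0.12 without 33 and -0.15 without 3033. Of the genes AMG B changed, the same sign under AMG A was seen for 56.8% in liver (of 849 among the 10411 genes in both tables), 59.5% in adrenal (of 1295) and 37.3% in pancreas (of 1719). In liver 3 genes rose and 2 fell with both, where 0.922 and 0.604 were expected. The 3 mg/kg count was 1 without animal 3012, 28 or 32 in adrenal and 1 without animal 30 in pancreas. The high-dose count was 178 without animal 3012, 200 without 3010 and 202 without 25 in adrenal, and 322 without animal 3009, 368 without 26, 370 without 3036, 423 without 3035, 430 without 3033 and 474 without 33 in pancreas. Between controls it was 105 without animal 3012, 110 without 27, 114 without 28, 133 without 3010, 152 without 25 and 159 without 3011 in adrenal. In pancreas it was 1 without animal 3011, 2 without 3012, 4 without 3010, 5 without 27, 6 without 28, 7 without 3009 and 20 without 25. The calls of Tbl1x (10 of 16 omissions) and Msl1 (11 of 16 omissions) ended with 1 animal left out, at adjusted p from 0.0533 to 0.16. Another probe set of Tbl1x differed in the opposite direction, and the sign turned (0.085 with the mean of the probe sets).

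The same animals gave adrenal and pancreas on day 14, so the tissues' responses were compared directly. For AMG B 1146 genes differed (651 with the higher effect in adrenal, 495 with the lower), and 660 with the animal as a block. Slc2a1 (5.45, adjusted p = 0.00065) and Fdps (4.43, adjusted p = 0.00013) had the higher effect in adrenal, and Stac2 (-4.71, adjusted p = 0.00016) and N4bp2l1 (-4.92, adjusted p = 0.0022) the lower. In adrenal relative to pancreas, of 20 cholesterol synthesis genes 13 were higher, and adjusted over the list alone 16 (adjusted p = 1.4e-16, adjusted p = 0.24 with an estimated correlation). For AMG A, Tob1 (-2.42, adjusted p = 0.038) and Rsbn1 (-0.90, adjusted p = 0.014) were the 2 genes called, both with the lower effect in adrenal. With the animal as a block 0 were called. The AMG A count was 0 without the adrenal of 3009 or 3034 or the pancreas of 3010 and 1 without the adrenal of 3033, 3036, 3010, 3012 or 3035 or the pancreas of 3011. Without 1 pancreas it was 4 (3035), 6 (3012 or 3033), 7 (3036), 8 (3009) and 104 (3034). The calls of Tob1 (10 of 16 omissions) and Rsbn1 (without 3009, 3010 and 3034) ended with 1 animal left out, at adjusted p from 0.0538 to 0.12. Another probe set of Rsbn1 differed in the opposite direction, and the sign turned (0.20 with the filter on low scores and with the probe set of the highest mean).

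Vegfa, its receptors Kdr and Flt1 and the lymphatic receptor Flt4 were read in every tissue because of the stated pharmacology. In liver on day 14 at 60 mg/kg of AMG B Vegfa stood at 0.13 ± 0.31 against -0.46 ± 0.23 and Kdr at 0.57 ± 0.51 against 1.65 ± 0.26. Flt1 stood at 1.98 ± 0.57 against 1.32 ± 0.21 and Flt4 at -0.60 ± 0.14 against -0.44 ± 0.066, and none of the 4 passed (lowest adjusted p = 0.065, for Kdr). At 30 mg/kg of AMG A the lowest was adjusted p = 0.14, for Vegfa (-0.69 ± 0.11 against -0.92 ± 0.094). Adrenal Vegfa was 1.87 ± 0.76 against 1.12 ± 0.26, adjusted p = 0.17, and Kdr -0.998 ± 0.12 against -0.96 ± 0.062, adjusted p = 0.85, at 60 mg/kg of AMG B on day 14. At 30 mg/kg of AMG A the lowest in adrenal was adjusted p = 0.64, for Flt1 (0.13 ± 0.61 against 0.97 ± 0.082). In pancreas Flt1 was -0.73 ± 0.26 against -1.10 ± 0.56, adjusted p = 0.50, at 60 mg/kg of AMG B. Vegfa was -0.998 ± 0.20 against -0.98 ± 0.12, adjusted p = 0.99, at 30 mg/kg of AMG A. Another probe set of Flt1 and Vegfa differed in the opposite direction. The results depended on the probe set. With that of the highest mean, adrenal Kdr fell at 60 mg/kg of AMG B on day 1 (-1.40, adjusted p = 0.0058), day 4 (-2.83, adjusted p = 5.9e-09) and day 14 (-2.63, adjusted p = 5.4e-09), and at 3 mg/kg on day 4 (-1.89, adjusted p = 0.00019). The main day 4 values had the opposite sign (0.083 and 0.094). Adrenal Flt1 fell so at 60 mg/kg on day 1 (-1.85, adjusted p = 0.0076), but its day 4 call ended (-1.10, adjusted p = 0.14), as did that of Vegfa between the compounds in pancreas (-1.10, adjusted p = 0.099). With the mean of the probe sets, on day 14 at 60 mg/kg Kdr fell in liver (-1.34, adjusted p = 0.00042), Vegfa rose in adrenal (1.06, adjusted p = 0.036) and Kdr did not pass in pancreas (-0.60, adjusted p = 0.15). So read, adrenal Flt1 fell at 60 mg/kg on day 1 (-1.06, adjusted p = 0.040) and day 4 (-1.49, adjusted p = 0.00036) and at 3 mg/kg on day 4 (-1.26, adjusted p = 0.024), not on day 14. Which probe set follows the transcript was not tested.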

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

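The tests on acinar genes, on endothelial genes and on a failed array, the list test of a wrong dose label and the splits of whole animals were chosen after results were seen; the other splits and the other test of the dose label were written before.

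Acinar genes fell in pancreas at 60 mg/kg of AMG B, 23 of 27 of them. With the array SD as a covariate 23 members were still past the threshold, which argues against unequal spread of the arrays as the whole cause. A lower share of acinar cells would raise the markers of every other type alike. Of endothelial and islet members 8 were lower and 0 higher (5 lower without animal 25, 27 or 35), with medians of -0.17 and -0.026. This cannot decide, since AMG B lowered endothelial genes in liver and adrenal too. With any 1 animal left out at least 22 acinar members were past the threshold, against a single animal as the cause. Of pericyte, matrix and duct members 7 rose and 2 fell (1 rose without animal 26, 3 without 25, 27 or 28 and 14 without 34), and animal 35 was the highest in matrix (3.78, others 0.29 to 2.39) and duct means (3.25, others 0.56 to 1.65). More of those cells cannot be told apart from a response of the acinar cells to the compound, given in the design, because scores do not size a share of cells. Loss of acinar cells was not tested apart from either.

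Endothelial genes fell in adrenal at 60 mg/kg of AMG B on day 4. After quantile normalization 11 members were past the threshold and lower, which argues against array scaling, and with 1 animal left out the fewest was 5. Dilution by a growing cortex would lower medulla genes too, by an unknown amount. Their median was 0.48 (endothelial -0.83), with quartiles of 0.018 and 0.72 and 14 of 17 above 0. With 1 animal left out the lowest was 0.25, without animal 22. No rise of the medulla is claimed, since 1 member passed and the list did not with an estimated correlation (adjusted p = 0.23) or without animal 22. Fewer endothelial cells and lower transcription within them may each remain and were not tested apart.

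Animal 35 stood apart from its group of 60 mg/kg on day 14. Its deviations in liver and adrenal correlated at 0.136 across genes, narrowly above the highest value of different animals (0.116). This cannot decide on a failed array. Deviations from a group mean lower the correlations of different animals, and animal 29 (3 mg/kg day 14) had 0.133. For a wrong dose label, 57.88% of genes lay on the treated side in liver, between the bounds of 50 and 75 percent written beforehand, which cannot decide. In 3 responding lists 93.48% of called members lay beyond every control and 3 mg/kg array. These were 6 of 7 drug-metabolising enzymes in liver, 15 of 17 cholesterol synthesis genes in adrenal and 22 of 22 acinar genes in pancreas. For these members this argues against a wrong dose label. Its liver macrophage (0.80) and adrenal endothelial means (1.06) lay near or above controls, so not every list went with the dose. Its Lcn2, an acute phase gene, was 8.54 in liver, its Timp1 10.8 in adrenal and its Cyp2c11 -0.78 in liver against 0.81 to 1.00 in the other 3, values chosen after they were seen. A failed array may remain, as may a sick or more strongly affected animal, which was not tested.

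An array lay far from the other 3 of its group in 28 of 240 tests (11.67%), where chance gives about 1 in 20. Tested were the SD and deviation of arrays, Vegfa, Kdr, Flt1 and Flt4, and 4 list means in pancreas. A and B are AMG A and AMG B, followed by the dose in mg/kg. The SD of the scores was 0.847 in animal 18 (adrenal B 3 day 4), 0.895 in animal 16 (adrenal B control day 4) and 0.831 in animal 6 (liver B 3 day 1). It was 0.831 in animal 24 (liver B 60 day 4) and 0.856 in animal 26 (liver B control day 14). The deviation from the group was 1.495 in animal 35 (adrenal B 60 day 14), 0.896 in animal 9 (liver B 60 day 1) and 1.45 in animal 35 (liver B 60 day 14). It was 1.36 in animal 30 (pancreas B 3 day 14) and 1.16 in animal 33 (pancreas B 60 day 14). Vegfa was -0.84 in animal 3035 (liver A 30 day 14), 1.61 in animal 30 (adrenal B 3 day 14) and 0.063 in animal 3 (adrenal B control day 1). Kdr was -0.48 in animal 3011 (liver A control day 14), -0.84 in animal 3033 (adrenal A 30 day 14) and -1.17 in animal 35 (adrenal B 60 day 14). It was -0.52 in animal 24 (adrenal B 60 day 4) and -0.71 in animal 33 (pancreas B 60 day 14). Flt1 was -0.96 in animal 3035 (liver A 30 day 14). Flt4 was -0.69 in animal 6 (liver B 3 day 1) and 0.052 in animal 27 (pancreas B control day 14). The skeletal muscle mean was 1.88 in animal 3009 (pancreas A control day 14) and 6.84 in animal 3036 (pancreas A 30 day 14). It was 0.61 in animal 30 (pancreas B 3 day 14) and 3.14 in animal 36 (pancreas B 60 day 14). The lymphocyte mean was 3.41 in animal 3034 (pancreas A 30 day 14) and 4.12 in animal 33 (pancreas B 60 day 14). The adipocyte mean was 2.13 in animal 28 (pancreas B control day 14).

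Effects differed between groups by the direct test in 42 genes between days 14 and 1 in liver of AMG B and 303 in adrenal. Compounds differed in 3 genes at 3 mg/kg and 309 at the high doses in adrenal and 733 in pancreas, and adrenal and pancreas effects in 2 genes for AMG A and 1146 for AMG B (0 and 660 with the animal as a block).

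How often other groupings of the same arrays gave as many genes was counted for each contrast, with 35 splits or, for differences of effects, 100 permutations. Values in parentheses are the real count and the highest other. Where 1 of 35 splits, the real one, had a count as large (the fewest possible), chance is unlikely, unadjusted over contrasts. This covers liver A 30 day 1 (36, 3), A 30 day 4 (4, 2), A 30 day 14 (38, 5) and B 60 day 1 (17, 3). This holds for liver B 60 day 4 (120, 8), B 60 day 14 (1041, 172), A 30 minus 3 day 14 (13, 6) and B 60 minus 3 day 14 (747, 163). It holds for adrenal B 60 day 1 (34, 21), B 60 day 4 (150, 35), B 60 day 14 (1295, 191), B 60 minus 3 day 14 (1006, 462) and A minus B controls (242, 3). This also holds for pancreas B 60 (1719, 2), B 60 minus 3 (713, 70) and A minus B controls (11, 1). All 35 splits reached a real count of 0. The splits leave chance open for liver A 3 day 1 (0, 73), A 3 day 14 (0, 3), B 3 day 1 (0, 1) and B 3 day 14 (0, 3). They leave it open for adrenal A 30 day 14 (0, 4) and A 30 minus 3 day 14 (0, 170). It is open for pancreas A 3 (0, 1), A 30 (0, 1), B 3 (0, 3) and A 30 minus 3 (0, 0). Chance cannot be excluded in liver A 3 day 4 (5 of 35 as large, 1, 2), liver B 3 day 4 (6 of 35 as large, 2, 4) and adrenal A 3 day 14 (14 of 35 as large, 2, 68). Nor can it in adrenal B 3 day 1 (11 of 35 as large, 1, 8), adrenal B 3 day 4 (4 of 35 as large, 6, 47) and adrenal B 3 day 14 (6 of 35 as large, 4, 15). Permutations make chance unlikely for liver B 60 day 14 minus 1 (1 of 100 as large, 42, 12) and adrenal B 60 day 14 minus 1 (1 of 100 as large, 303, 135). They also make it unlikely for adrenal A minus B high dose (1 of 100 as large, 309, 108) and pancreas A minus B high dose (1 of 100 as large, 733, 4). They do not for adrenal A minus B 3 (9 of 100 as large, 3, 26). A real count of 0 is reached by any permutation, so they leave it open for liver A 30 day 14 minus 1 (100 of 100 as large, 0, 1) and pancreas A minus B 3 (100 of 100 as large, 0, 1). For adrenal minus pancreas, whose arrays share animals, permutations of single arrays gave 2 of 100 as large for A (2, 7) and 1 of 100 as large for B (1146, 14). With the 2 arrays of an animal moved together, 4 of 35 splits were as large for A (2, 4) and 1 of 35 splits were as large for B (1146, 1). Chance is thus unlikely for B and left open for A, where the fit with the animal as a block called 0. Some other splits called far more genes than the real one, for a cause not tested, as in liver A 3 day 1 (73), adrenal A 3 (68) and A 30 minus 3 (170). This was also seen in adrenal for B 3 day 1 (8), day 4 (47) and day 14 (15) and A minus B 3 (26).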

How the results depend on the processing

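The log-like scale, the probe set with the highest mean, the array SD as covariate and the fits without arrays high in lymphocyte markers were chosen after seeing the data. Of 594 calls of named genes, 477 held after quantile normalization and 117 were lost. There were 501 that held with the filter on low scores, 508 with the mean of the probe sets, 528 with the probe set of the highest mean, 407 on the log-like scale and 144 with only the compared groups fitted. With 1 animal left out, 4246 gene calls held and 1522 were lost. Of 215 list calls at the preset correlation, 12 held with the estimated correlation. The median difference of all genes passed 0.1 units after quantile normalization in pancreas for AMG A minus AMG B at the high dose (-0.11) and there with the filter at 3 mg/kg (0.10). The pseudocount alternative was not run. Scores give no signal over background, so what dimness limits cannot be read from them.

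A and B are AMG A and AMG B, the number after them is the dose in mg/kg, and pancreas is day 14. Each value is the number of genes called where it moved by over 1.5 times. With only the compared groups fitted liver counts were 5 for A 3 day 1, 10 for A 30 day 1, 0 for A 3 day 4, 13 for A 30 day 4, 6 for A 3 day 14 and 19 for A 30 day 14. They were 61 for B 60 day 4, 1 for B 3 day 14, 54 for B 60 day 14, 0 for A 30 minus 3 day 14, 6 for B 60 minus 3 day 14 and 3 for B 60 day 14 minus 1. Adrenal counts were 0 for A 3 day 14, 9 for B 60 day 1, 1 for B 3 day 4, 15 for B 60 day 4, 0 for B 3 day 14 and 158 for B 60 day 14. They were 4 for B 60 minus 3 day 14, 69 for B 60 day 14 minus 1, 0 for A minus B 3, 57 for A minus B high dose and 88 for A minus B controls. Pancreas counts were 857 for B 60, 5 for B 60 minus 3 and 1 for A minus B controls, and the AMG A contrast of adrenal minus pancreas gave 0. These fits have fewer arrays to estimate the spread of a gene, but the cause was not tested. On a log-like scale liver counts were 23 for A 30 day 1, 0 for A 3 day 4, 15 for A 30 day 14, 9 for B 60 day 1, 0 for B 3 day 4, 5 for A 30 minus 3 day 14 and 1 for B 60 day 14 minus 1. Adrenal counts were 0 for A 3 day 14, 1 for A 30 day 14, 0 for B 3 day 1, 55 for B 60 day 1 and 3 for B 3 day 4. They were 266 for B 60 day 4, 119 for B 60 day 14 minus 1, 122 for A minus B high dose and 102 for A minus B controls. Pancreas counts were 392 for B 60 minus 3, 425 for A minus B high dose and 0 for A minus B controls. Adrenal minus pancreas gave 0 for A and 665 for B. After quantile normalization liver counts were 0 for A 3 day 4, 1 for B 3 day 4 and 21 for B 60 day 14 minus 1. Adrenal counts were 1 for A 3 day 14, 3 for B 3 day 1, 75 for B 60 day 1, 603 for B 60 minus 3 day 14 and 1 for A minus B 3. Pancreas counts were 2 for A 30, 1 for B 3 and 5 for A minus B controls, and A adrenal minus pancreas gave 0. With the filter on low scores liver counts were 2 for A 3 day 1, 15 for A 30 day 1, 1 for B 3 day 1, 4 for B 3 day 4 and 8 for A 30 minus 3 day 14. Adrenal counts were 1 for A 3 day 14, 0 for B 3 day 1, 22 for B 60 day 1 and 0 for A minus B 3. Pancreas counts were 2 for A 30 and 454 for B 60 minus 3, and A adrenal minus pancreas gave 0. With the mean of the probe sets liver counts were 3 for A 3 day 1, 25 for A 30 day 14 and 1 for B 3 day 1. Adrenal counts were 0 for A 3 day 14, 3 for B 3 day 1 and 1 for A minus B 3. Pancreas counts were 3 for A 30, and A adrenal minus pancreas gave 0. With the probe set of the highest mean liver counts were 2 for B 3 day 1. Adrenal counts were 0 for A 3 day 14 and 0 for A minus B 3, and A adrenal minus pancreas gave 0. With the array SD as covariate pancreas counts were 2 for B 3, 1 for A minus B 3, 448 for A minus B high dose and 2 for A minus B controls. Without the arrays high in lymphocyte markers pancreas counts were 2 for A 30, 268 for A minus B high dose and 0 for A minus B controls. With the animal as a block adrenal minus pancreas gave 0 for A and 660 for B. The share of rises among called genes depended on the scale. In contrasts with over 30 calls its majority turned on the log-like scale for liver A 30 day 14 (63.16 to 40%), B 60 day 4 (61.67 to 49.07%) and B 60 minus 3 day 14 (56.36 to 44.31%). It turned there for adrenal B 60 minus 3 day 14 (51.49 to 41.62%), A minus B high dose (47.57 to 58.2%) and A minus B controls (40.91 to 57.84%), and for pancreas B 60 (55.09 to 46.05%), B 60 minus 3 (69.14 to 49.23%) and A minus B high dose (49.52 to 59.53%). On that scale it also fell for B 60 day 14 in liver (48.32 to 35.3%) and adrenal (49.58 to 37.36%). Quantile normalization gave 63.68% for pancreas B 60, 75.04% for B 60 minus 3 and 39.38% for A minus B high dose, and turned liver B 60 minus 3 (49.82%), adrenal A minus B high dose (55.95%) and B adrenal minus pancreas (56.81 to 48.81%). For pancreas B 60 the share was 45.65% with the filter, 47.74% with the probe set of the highest mean and 47.84% with only the compared groups. For pancreas A minus B high dose it was 57.77%, 56.64% and 50.8% with these. With the compared groups it also turned for liver A 30 day 14 (36.84%) and adrenal A minus B high dose (50.88%). With the filter it turned for adrenal B 60 day 14 (50.48%) and B 60 minus 3 (49.72%), and with the mean of the probe sets for B 60 day 14 in liver (51.16%) and adrenal (51.37%). The cause was not tested for any of these.

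Each animal was also left out in turn. Liver counts ran from 0 to 26 for A 3 day 1, 9 to 75 for A 30 day 1, 0 to 3 for A 3 day 4 and 1 to 9 for A 30 day 4. They were 0 to 3 for A 3 day 14, 7 to 118 for A 30 day 14, 0 to 0 for B 3 day 1 and 9 to 16 for B 60 day 1. They were 1 to 5 for B 3 day 4, 50 to 142 for B 60 day 4, 0 to 6 for B 3 day 14 and 664 to 1038 for B 60 day 14. They were 1 to 35 for A 30 minus 3 day 14, 360 to 838 for B 60 minus 3 day 14, 0 to 1 for A 30 day 14 minus 1 and 12 to 98 for B 60 day 14 minus 1. Adrenal counts ran from 0 to 4 for A 3 day 14, 0 to 3 for A 30 day 14, 0 to 2 for B 3 day 1, 22 to 34 for B 60 day 1 and 2 to 18 for B 3 day 4. They were 79 to 230 for B 60 day 4, 2 to 11 for B 3 day 14, 870 to 1485 for B 60 day 14, 0 to 2 for A 30 minus 3 day 14 and 744 to 1260 for B 60 minus 3 day 14. They were 185 to 457 for B 60 day 14 minus 1, 1 to 4 for A minus B 3, 178 to 446 for A minus B high dose and 105 to 219 for A minus B controls. Pancreas counts ran from 0 to 0 for A 3, 0 to 31 for A 30, 0 to 4 for B 3, 1001 to 1596 for B 60 and 0 to 0 for A 30 minus 3. They were 302 to 855 for B 60 minus 3, 0 to 1 for A minus B 3, 322 to 1096 for A minus B high dose and 1 to 20 for A minus B controls. Adrenal minus pancreas counts ran from 0 to 104 for A and 795 to 1222 for B. The correlation of the compounds' effects across genes ran from 0.044 to 0.10 in liver, 0.031 to 0.12 in adrenal and -0.31 to -0.048 in pancreas. The cause was not tested.

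With the probe set of the highest mean, the sign turned for Cd44 (0.067) and Asrgl1 (1.70) in liver A 30 day 14. It turned for Sox17 (0.25) and Pgk1 (0.73) in liver B 60 day 14 and Xrn2 in adrenal B 60 day 1 (-0.043). It turned for Mvk (-0.82) and Fasn (-0.073) in pancreas B 60 and Kif5a in liver A 30 minus 3 day 14 (0.14). For B 60 minus 3 day 14 it turned for Pgk1 in liver (0.84) and Aif1 in adrenal (0.014). For A minus B controls it turned for Jchain in adrenal (-0.0048) and Prpf3 in pancreas (-0.000642). It turned for Mvk (0.60) and Clu (0.82) in pancreas A minus B high dose. It turned for Rsbn1 in A (0.20) and Per2 in B adrenal minus pancreas (-0.019). With the mean of the probe sets, the sign turned for Asrgl1 in liver A 30 day 14 (0.61), Tbl1x in adrenal B 3 day 14 (-0.057), Mvk in pancreas B 60 day 14 (-0.59) and Pgk1 in liver B 60 minus 3 day 14 (0.22). It turned for Tbl1x in adrenal A minus B 3 (0.085), Mvk in pancreas A minus B high dose (0.44) and Kdr in B adrenal minus pancreas (-0.73). With the filter on low scores, the sign turned for Afg2b (0.0070) and Sox17 (0.25) in liver B 60 day 14 and Mvk in pancreas B 60 (-0.82). It turned for Afg2b in liver B 60 minus 3 day 14 (0.042), Mvk in pancreas A minus B high dose (0.60) and Rsbn1 in A adrenal minus pancreas (0.20). After quantile normalization, the sign turned for acinar cells in pancreas A minus B 3 (adjusted p = 0.62) and A minus B controls (adjusted p = 0.027). Lymphocytes turned without animal 3009 in pancreas A 30 day 14 (adjusted p = 0.95, range with 1 animal left out 7.9e-05 to 0.95) and A adrenal minus pancreas (adjusted p = 0.95, range 0.00013 to 0.95). Extracellular matrix and fibroblasts turned without animal 35 in adrenal B 60 day 14 (adjusted p = 0.034, range with 1 animal left out 8.4e-07 to 0.034). They did so in adrenal B 60 minus 3 day 14 (adjusted p = 0.0025, range 4.9e-07 to 0.0038) and A minus B high dose (adjusted p = 0.015, range 4.6e-05 to 0.020). Cell cycle turned without animal 35 in liver B 60 day 14 (adjusted p = 0.98, range 9.5e-05 to 0.98) and B 60 minus 3 day 14 (adjusted p = 0.95, range 5.1e-05 to 0.95). The cause was not tested.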

Other observations

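All values here come from planned contrasts, and no test was chosen after the results were seen. Which genes and lists to print was chosen after that. In adrenal at 60 mg/kg of AMG B on day 14 the opioid precursor Penk (1.21 ± 2.86 against -0.59 ± 0.15, adjusted p = 0.0474) and the receptor Ret (0.57 ± 1.25 against -0.43 ± 0.033, adjusted p = 0.0081) rose. Of 17 genes of the catecholamine-making medulla 2 rose, and adjusted over the list alone 2 (adjusted p = 0.97, adjusted p = 0.98 with an estimated correlation). The median difference of that list was -0.20, its mean 0.060 and the direction of its test up. In pancreas at the same dose the immediate early gene Egr1 (2.14 ± 1.12 against -0.56 ± 0.19, adjusted p = 0.0094) rose. Of matrix genes Thbs2 fell (0.92 ± 0.34 against 2.92 ± 1.11, adjusted p = 0.0022). Of 18 matrix genes in pancreas 3 rose and 1 fell, and adjusted over the list alone 3 rose and 1 fell (adjusted p = 0.064, adjusted p = 0.85 with an estimated correlation). The call of Penk (5 of 8 omissions) ended with 1 animal left out, at adjusted p from 0.070 to 0.22.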
